A study of Mus musculus with 60 samples.

How the data were processed

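PolyA RNA was sequenced from GFP-sorted epithelial cells of 8-week-old mice that carry an Lgr5-2A-eGFP allele. Per the labels, cells were released by chelation and TrypLE digestion, at least 30000 cells per colon fraction and 50000 per small intestinal fraction were sorted, and RNA was purified with a micro column kit. The 5 gut parts, 3 GFP fractions and 4 replicates give 15 groups of 4 libraries.

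The deposited table lists 55357 genes per library, 21833 of them protein coding, with counts and several derived columns. The counts are whole, unnormalised counts per gene and library as deposited, and they were the only measurement used. Per the submitters' processing notes, STAR, Subread featureCounts and edgeR were used with the mm10 build, without versions; the library kit, the strandedness and the annotation release are not stated. The deposited columns of log2 RPKM, log2 CPM, log2 TPM, library size and normalization factor were left out, since each derives from the counts. The other deposited column used holds a batch number, which equals the replicate number in 60 of 60 libraries. Only 35 gene identifiers match the reference annotation at hand with their version and 52081 without it, so the annotation releases differ and no coordinates are given.

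The equal numbers were read as pairing the libraries across groups (from the deposited table). As a check, residual correlations over 8000 genes averaged 0.168 over the 420 pairs of libraries with the same number, 58.8% of them above 0.1, and -0.052 over pairs with different numbers. The mean between 2 groups compared ran from -0.201 (lowest pair -0.759) for GFP-high with GFP-negative of the proximal colon to 0.627 for GFP-high with GFP-intermediate of the proximal small intestine. It was -0.003, with 0 of 4 pairs above 0.1, for GFP-high of proximal colon and proximal small intestine. The pairing thus does not show alike between all groups, and Y-linked Ddx3y argues against it across organs for number 1. The replicate number was a block in 1 alternative, given where it changes the call.

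Genes were kept by edgeR's filterByExpr over the 15 groups, which left 23360 genes with 99.97% to 99.99% of each library's counts. Counts were scaled by TMM and fitted with the quasi-likelihood negative binomial model of edgeR 4.0.16 (glmQLFit in its default form, 45 residual and 5.43 prior degrees of freedom) over all 60 libraries, with limma 3.58.1 and R 4.3.3. There were 13 comparisons: GFP-high against GFP-negative in each part, GFP-high against GFP-intermediate over the colon and over the small intestine, distal against proximal colon in GFP-high and in GFP-negative cells, colon against small intestine and distal against proximal small intestine in GFP-high cells, and the interactions of fraction with colon part and with organ. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the genes of each comparison, and genes below 0.05 were called. The standard error is the log2 difference divided by the square root of its F statistic. Levels are CPM from edgeR's cpm function with TMM-scaled library sizes.

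The 28 gene lists, the comparisons, the rule for named genes and the alternatives were fixed before the data were examined, except where the closing section says otherwise. The lists cover stem, Wnt, cell cycle and lineage genes, Hox and other regional genes, oxidases, receptors and metabolism, and the leukocyte, stromal, erythroid and dissociation genes that a gate can carry along. The tuft, Paneth, immune cell and dissociation stress lists share no member with another list; the crypt base stem cell list shares 16 of 32. Lists were tested with camera at a preset inter-gene correlation of 0.01, which compares a list with all other genes, adjusted over the 364 list tests. Of these 173 were called, 34 with an estimated correlation (139 lost) and 180 with the replicate block (7 gained, 0 lost). Named genes were up to 10 genes per direction and comparison with the largest difference among those called, at 10 CPM or more on the higher side and with no overlap between the libraries of the 2 sides; Lgr5, Nox1 and Npy1r; up to 4 members per list and comparison with the smallest p; and 10 regional genes per colon part. A selection of these is printed, genes with 1 to 3 counts on one side are printed without a ratio or left out, and some genes are not reported here. Where one side had no count in any library, the ratio is given as a bound against a floor of 3 counts per library; the floor covers counting error only, since the reads carry no molecular identifiers.

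The alternatives were DESeq2 size factors, no filter on low counts (35853 genes), the DESeq2 1.42.0 Wald test, the replicate block, a fit of only the groups compared, a fold of at least 2 in addition, and each library left out in turn. Chance splits of the libraries used fits of only the groups compared. The pipeline was tested on simulated changes put into a comparison of distal with proximal colon GFP-high cells: of genes changed 1.5-fold, 26 of 67 (38.8%) were recovered, of those changed 2-fold 48 of 67 (71.6%) and of those changed 4-fold 64 of 66 (97%), with 10 unchanged genes called among 22596. The 38 cell cycle genes, raised 2-fold, gave a list test of adjusted p = 2.76e-81, and 0 other lists were called. The simulated genes were drawn independently of each other, so this cannot show how the list tests behave where genes are correlated. Data were read with Python 3.11.15 and numpy 2.4.6 and plotted with matplotlib 3.10.9; in R they were read with the package data.table, version 1.17.8.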

Results

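The measurements were polyA RNA-seq of epithelial cells from 8-week-old mice in which eGFP is expressed together with Lgr5, the R-spondin receptor gene that marks crypt base stem cells. The small intestine was taken as 3 equal parts and the colon as 2, and the cells of each part were sorted into GFP-high, GFP-intermediate and GFP-negative fractions. Each of the 15 groups had 4 libraries, 60 in all. Total counts ran from 55411864 to 113917959 per library, with a median of 81230235, and between 18419 and 23453 genes had at least 1 count. Differences below are log2 ratios with their standard errors, from 4 libraries on each side within a gut part, 8 per fraction over the colon and 12 per fraction over the small intestine; a gene is called at an adjusted p below 0.05. Levels are library-size normalised counts (CPM), given as mean ± SD with n = 4.

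The fractions followed Lgr5 in every gut part, and Nox1, the superoxide-generating NADPH oxidase of the colon epithelium, was higher in GFP-high than in GFP-negative cells throughout. The Lgr5 level (ENSMUSG00000020140.16) in GFP-high cells was 312 ± 61.4 CPM in the proximal, 436 ± 38.8 CPM in the middle and 544 ± 48.7 CPM in the distal small intestine, 264 ± 54.4 CPM in the proximal colon and 203 ± 39.7 CPM in the distal colon. GFP-negative cells held 2.67 ± 0.675 CPM in the proximal small intestine and 12.2 ± 3.68 CPM in the proximal colon, so the log2 differences ran from 4.44 ± 0.30 in the proximal colon (adjusted p = 7.82e-16) and 4.97 ± 0.31 in the distal colon (adjusted p = 3.14e-17) over 6.87 ± 0.34 and 7.20 ± 0.35 to 7.46 ± 0.35 in the distal small intestine (adjusted p = 3.32e-23). Nox1 (ENSMUSG00000031257.15) stood at 5.01 ± 4.51, 35.8 ± 19.98 and 83.5 ± 14.5 CPM in the GFP-high cells of the proximal, middle and distal small intestine and at 133 ± 32.3 and 296 ± 55.7 CPM in those of the proximal and distal colon. It was higher in GFP-high than in GFP-negative cells of all 5 parts, by 2.06 ± 0.57 (adjusted p = 0.00243), 3.18 ± 0.56 (adjusted p = 3.89e-06) and 4.33 ± 0.59 (adjusted p = 1.36e-08) down the small intestine and by 2.24 ± 0.53 (adjusted p = 0.00111) and 2.32 ± 0.53 (adjusted p = 0.000807) down the colon. In the proximal small intestine it was 1.43 without GFP-high and 2.83 without GFP-negative replicate 4. The call ended with only the groups compared (adjusted p = 0.0717).

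Npy1r (ENSMUSG00000036437.7), a receptor for neuropeptide Y and peptide YY, was highest in the GFP-high cells of the distal colon. Its level there was 72.3 ± 14.4 CPM in GFP-high, 41.03 ± 4.64 CPM in GFP-intermediate and 17.3 ± 2.02 CPM in GFP-negative cells, a GFP-high excess of 2.06 ± 0.51, adjusted p = 0.00202. In the proximal colon it was 4.62 ± 2.39 CPM in GFP-high, 2.81 ± 1.38 CPM in GFP-intermediate and 11.2 ± 5.91 CPM in GFP-negative cells. GFP-high against GFP-negative cells was not called there (-1.27 ± 0.50, adjusted p = 0.0576), but the difference between the colon parts in this contrast was itself called (3.33 ± 0.72, adjusted p = 0.0103). The proximal colon value was called with the replicate number as a block (-1.31, adjusted p = 0.0268), with DESeq2 size factors (adjusted p = 0.0482), under the newer quasi-likelihood method (adjusted p = 0.00061), and without GFP-high replicate 3 (adjusted p = 0.0464), GFP-high replicate 4 (adjusted p = 0.0489) or GFP-negative replicate 2 (adjusted p = 0.0493). It was not called without the libraries numbered 1 (-1.16, adjusted p = 0.147), by the DESeq2 Wald test (adjusted p = 0.157), without a filter (adjusted p = 0.0677), with only the groups compared, or without the other 5 libraries in turn, and lay at -0.83 (adjusted p = 0.281) without GFP-negative replicate 3. The difference between the parts was not called without proximal colon GFP-negative replicate 3 (2.89, adjusted p = 0.0514), without the libraries numbered 1 (adjusted p = 0.06) or by the DESeq2 Wald test (adjusted p = 0.0617). No small intestinal library reached 1 CPM of Npy1r, and the highest stood at 0.933 CPM; at these levels it was called lower in GFP-high than in GFP-negative cells of the proximal, middle and distal parts (adjusted p = 0.00238, 5.49e-05 and 0.000186), in the proximal part not under the newer quasi-likelihood method (adjusted p = 0.0669).

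**Figure D1:**
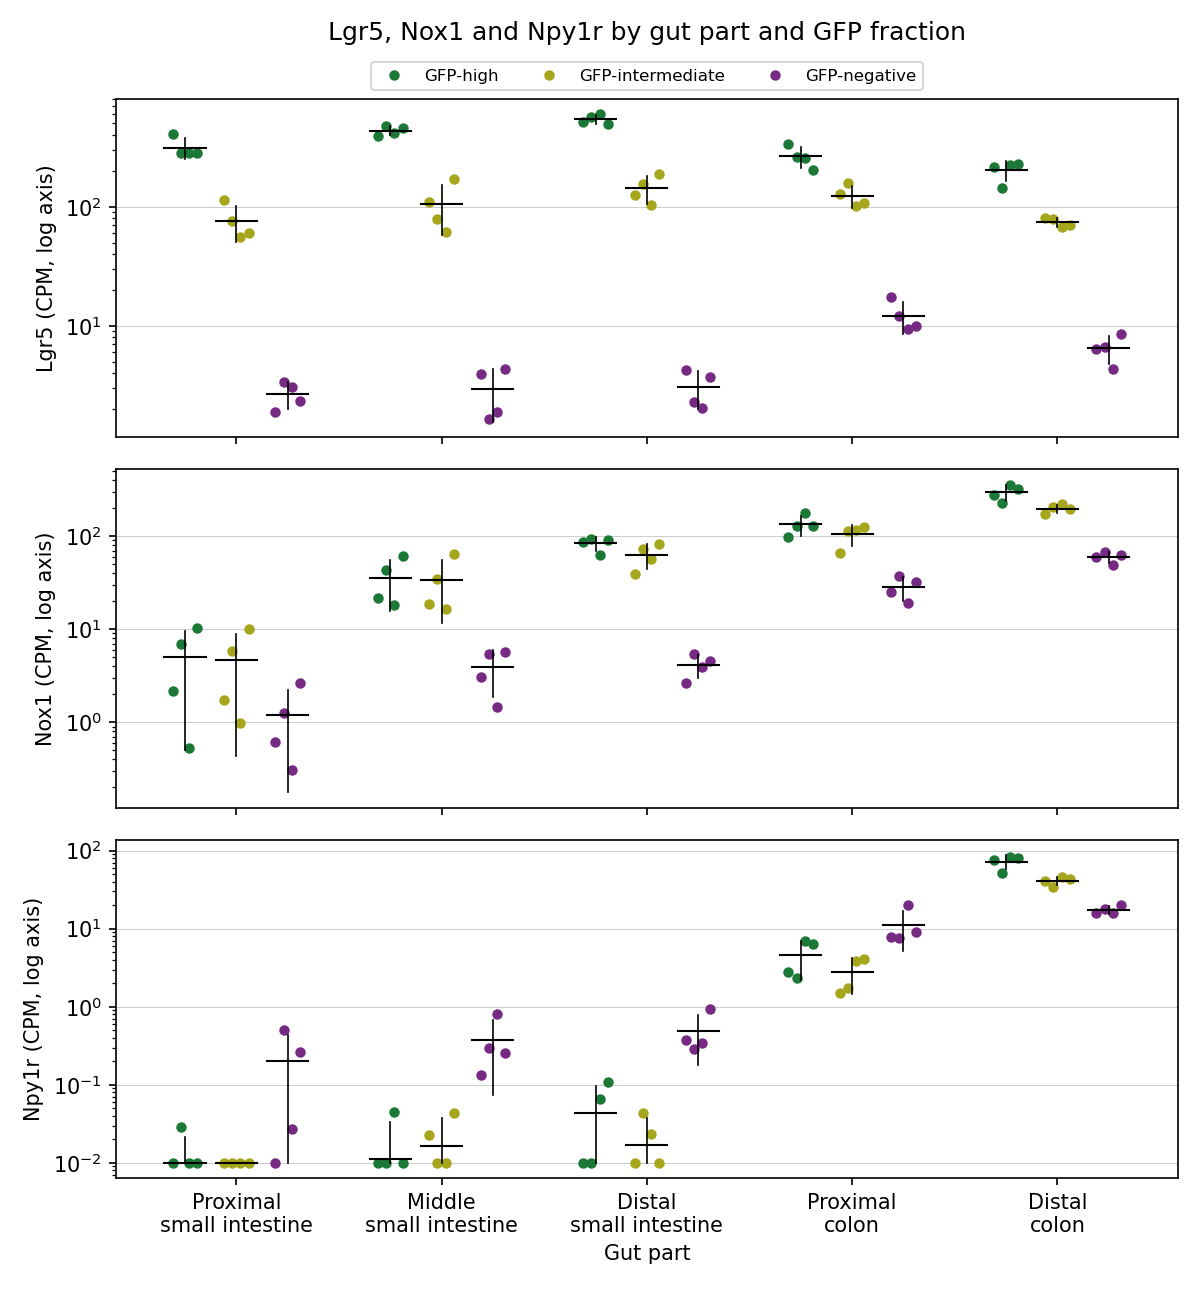
Normalised counts (CPM) of Lgr5, Nox1 and Npy1r in each of the 60 libraries by gut part and GFP fraction, on a log axis; points are libraries, horizontal bars the mean and vertical bars the SD of 4, and values below 0.01 are drawn there. Lgr5 orders the fractions in each part, Nox1 in GFP-high cells runs from a mean of 5.01 CPM in the proximal small intestine to 296 CPM in the distal colon, and Npy1r reaches 72.3 CPM in distal colon GFP-high cells.

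In the small intestine, GFP-high cells differed from GFP-negative cells by a stem and cycling program on one side and enterocyte, goblet and leukocyte genes on the other. The stem genes Tnfrsf19, a receptor of the tumour necrosis factor family that Wnt signalling induces, and Cdca7, a cell division-associated gene, rose in the proximal part by 6.57 ± 0.34 (adjusted p = 8.68e-22) and 3.12 ± 0.14 (adjusted p = 3.13e-24). The kinesin gene Kif26b rose by 6.56 ± 0.66 in the middle part (adjusted p = 5.31e-12). In the distal part Tnfrsf19 rose by 6.51 ± 0.32 (adjusted p = 1.74e-22) and Olfm4, a secreted glycoprotein of crypt base cells, by 6.31 ± 0.90 (adjusted p = 3.97e-08). Mttp, which loads lipid onto chylomicrons, fell by 3.37 ± 0.26 in the proximal part (adjusted p = 2.63e-15), and Zg16, a lectin of goblet cell granules, fell by 5.27 ± 0.45 (adjusted p = 5.39e-14).

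The gene lists were counted in each of the 3 parts; values are for the proximal, middle and distal part in turn, and a single value held in each. Of the crypt base stem cell list, 31 of the 32 rose, 0 fell and 1 was not called (31, 31 and 32 rose adjusted over the list alone). The crypt base stem cell list tested at adjusted p = 1.35e-29, 4.74e-31 and 1.53e-28, and at adjusted p = 0.00053, 0.000509 and 0.00053 with an estimated correlation. Of the Wnt target list, 18, 17 and 17 of the 24 rose, 1, 2 and 3 fell and 5, 5 and 4 were not called (18, 17 and 18 rose adjusted over the list alone). The Wnt target list tested at adjusted p = 1.72e-10, 5.98e-10 and 8.77e-10, and at adjusted p = 0.0085, 0.0106 and 0.0113 with an estimated correlation. Of the cell cycle genes, 37 of the 38 rose, 0 fell and 1 was not called (38 rose adjusted over the list alone). The cell cycle list tested at adjusted p = 6.18e-13, 3.33e-14 and 1.27e-17, and at adjusted p = 0.296, 0.26 and 0.19 with an estimated correlation. Of the ribosome biogenesis genes, 19, 18 and 18 of the 20 rose, 0 fell and 1, 2 and 2 were not called (19, 18 and 18 rose adjusted over the list alone). The ribosome biogenesis list tested at adjusted p = 2.52e-14, 1.47e-13 and 6.21e-14, and at adjusted p = 0.0615, 0.0642 and 0.0615 with an estimated correlation. Of the enterocyte genes, 28 of the 28 fell, 0 rose and 0 were not called (28 fell adjusted over the list alone). The enterocyte list tested at adjusted p = 2.14e-16, 7.67e-15 and 5.36e-15, and at adjusted p = 0.0528, 0.0615 and 0.0615 with an estimated correlation. Of the goblet genes, 20, 19 and 20 of the 23 fell, 1, 0 and 0 rose and 2, 4 and 3 were not called (20, 19 and 20 fell adjusted over the list alone). The goblet list tested at adjusted p = 1.66e-09, 1.4e-09 and 2.63e-09, and at adjusted p = 0.13, 0.13 and 0.135 with an estimated correlation. Of the surface colonocyte genes, 18, 18 and 19 of the 25 fell, 1, 1 and 2 rose and 6, 6 and 4 were not called (18, 18 and 20 fell adjusted over the list alone). The surface colonocyte list tested at adjusted p = 8.34e-07, 2.08e-05 and 8.61e-06, and at adjusted p = 0.144, 0.219 and 0.199 with an estimated correlation. Of the enteroendocrine genes, 18, 21 and 21 of the 27 fell, 0, 0 and 1 rose and 9, 6 and 5 were not called (18, 22 and 21 fell adjusted over the list alone). The enteroendocrine list tested at adjusted p = 7.81e-05, 5.63e-06 and 0.000127, and at adjusted p = 0.374, 0.289 and 0.387 with an estimated correlation.

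Genes of 2 differentiated lineages rose with the stem genes. Of the Paneth list, 18 of the 20 rose, 1 fell and 1 was not called (19, 18 and 18 rose adjusted over the list alone). The Paneth list tested at adjusted p = 2.34e-08, 3.73e-10 and 4.46e-09, and at adjusted p = 0.0951, 0.0615 and 0.0785 with an estimated correlation. Lyz1, the Paneth lysozyme, had 5114 ± 1135, 9147 ± 4527 and 8869 ± 2338 CPM in GFP-high cells down the small intestine and 387 ± 90.9, 220.2 ± 68.8 and 179 ± 83.4 CPM in GFP-negative cells, a difference of 3.72 ± 0.46 in the proximal (adjusted p = 1.35e-09) and 5.38 ± 0.49 in the middle part (adjusted p = 3.92e-13). The mucosal pentraxin Mptx2 rose by 4.51 ± 0.50 in the proximal (adjusted p = 8.47e-11) and 6.61 ± 0.55 in the distal part (adjusted p = 1.7e-14), and the alpha-defensin Defa26 by 5.90 ± 0.51 in the middle part (adjusted p = 1.38e-11). Of the tuft list, 19, 17 and 18 of the 25 rose, 1, 1 and 2 fell and 5, 7 and 5 were not called (19, 17 and 19 rose adjusted over the list alone). The tuft list tested at adjusted p = 2.11e-07, 0.000342 and 2.61e-05, and at adjusted p = 0.277, 0.457 and 0.396 with an estimated correlation. The tuft kinase Dclk1 rose by 2.52 ± 0.30 in the proximal part (adjusted p = 7.75e-10), the cation channel Trpm5 by 2.73 ± 0.28 (adjusted p = 1.48e-11) and Siglecf, a sialic acid-binding lectin, by 3.31 ± 0.40 (adjusted p = 1.09e-09).

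The GFP-negative fractions of all parts carried leukocyte transcripts. Ptprc, the pan-leukocyte phosphatase CD45, averaged 188, 114 and 227 CPM in GFP-negative and 6.41, 5.95 and 15.6 CPM in GFP-high cells down the small intestine. Of the immune cell list, 24, 23 and 23 of the 25 fell, 0 rose and 1, 2 and 2 were not called (24, 23 and 24 fell adjusted over the list alone) in the small intestine. The immune cell list tested at adjusted p = 1.5e-11, 2.91e-10 and 1.6e-13, and at adjusted p = 0.0956, 0.124 and 0.0667 with an estimated correlation. Il2rb, a lymphocyte cytokine receptor, fell by 7.47 ± 0.84 in the middle (adjusted p = 1.44e-10) and Cd8a, a T cell coreceptor, fell by 8.91 ± 0.95 in the distal part (adjusted p = 2.57e-11; -9.75 without distal small intestine GFP-high replicate 2). The counts of called genes were 11013 (5266 higher, 5747 lower) in the proximal, 11290 (5304 higher, 5986 lower) in the middle and 12137 (6006 higher, 6131 lower) in the distal part, of 23360 tested.

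In both colon parts, GFP-high cells were higher in stem and cell cycle genes and lower in enteroendocrine and leukocyte genes. Smoc2, a matricellular protein of stem cells, rose by 3.85 ± 0.15 in the proximal (adjusted p = 4.44e-26) and 3.17 ± 0.15 in the distal colon (adjusted p = 7.34e-23). Ascl2, the transcription factor of the crypt base, rose by 3.23 ± 0.35 (adjusted p = 8.51e-10) and 3.14 ± 0.35 (adjusted p = 2.56e-09), the sodium channel subunit Scn2b by 3.97 ± 0.31 (adjusted p = 6.16e-14) and 3.69 ± 0.31 (adjusted p = 1.1e-12), and Rgcc, a cell cycle regulator, by 3.18 ± 0.40 (adjusted p = 1.97e-08) and 3.24 ± 0.40 (adjusted p = 2.44e-08). Cps1, the first enzyme of the urea cycle, rose by 4.10 ± 0.24 in the proximal colon (adjusted p = 3.02e-18) and Angpt2, an angiopoietin, by 3.94 ± 0.31 in the distal colon (adjusted p = 1.72e-13). Nusap1, a mitotic spindle protein, rose by 1.92 ± 0.26 (adjusted p = 1.76e-07) and 1.63 ± 0.26 (adjusted p = 4.79e-06).

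Values for the lists are for the proximal and the distal colon in turn, and a single value held in both. Of the crypt base stem cell list, 24 and 22 of the 32 rose, 3 and 1 fell and 5 and 9 were not called (24 and 23 rose adjusted over the list alone). Crypt base stem cell genes as a set gave adjusted p = 4.22e-18 and 1.03e-17, and adjusted p = 0.00776 and 0.0078 with an estimated correlation. Of the Wnt target list, 14 and 12 of the 24 rose, 5 and 4 fell and 5 and 8 were not called (14 and 13 rose adjusted over the list alone). Wnt target genes as a set gave adjusted p = 3.48e-06 and 7.73e-06, and adjusted p = 0.0623 and 0.0714 with an estimated correlation. Of the cell cycle genes, 37 and 36 of the 38 rose, 0 fell and 1 and 2 were not called (37 rose adjusted over the list alone). Cell cycle genes as a set gave adjusted p = 3.08e-25 and 3.07e-24, and adjusted p = 0.0997 and 0.106 with an estimated correlation. Of the ribosome biogenesis genes, 14 of the 20 rose, 0 fell and 6 were not called (14 and 15 rose adjusted over the list alone). Ribosome biogenesis genes as a set gave adjusted p = 2.77e-09 and 1.27e-11, and adjusted p = 0.141 and 0.0926 with an estimated correlation. Of the enteroendocrine list, 22 and 15 of the 27 fell, 0 rose and 5 and 12 were not called (22 and 18 fell adjusted over the list alone). Enteroendocrine genes as a set gave adjusted p = 6.3e-19 and 5.73e-07, and adjusted p = 0.0222 and 0.219 with an estimated correlation. Chga, a granin of hormone granules, fell by 5.55 ± 0.53 in the proximal colon (adjusted p = 2.35e-11) and Tph1, the serotonin synthesis enzyme, fell by 5.43 ± 0.48 (adjusted p = 3.93e-12). Of the goblet genes, 7 and 15 of the 23 fell, 0 rose and 16 and 8 were not called (7 and 17 fell adjusted over the list alone). Goblet genes as a set gave adjusted p = 0.00743 and 7.09e-11, and adjusted p = 0.533 and 0.0997 with an estimated correlation. The trefoil factor Tff3 fell by 2.78 ± 0.31 in the distal colon (adjusted p = 3.62e-09). Of the surface colonocyte genes, 11 and 12 of the 25 fell, 1 and 2 rose and 13 and 11 were not called (14 and 15 fell adjusted over the list alone). Surface colonocyte genes as a set gave adjusted p = 0.000286 and 0.000163, and adjusted p = 0.323 and 0.298 with an estimated correlation.

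Leukocyte genes were lower in the GFP-high cells of the colon too: of the immune cell list, 23 and 24 of the 25 fell, 0 rose and 2 and 1 were not called (23 and 24 fell adjusted over the list alone). Immune cell genes as a set gave adjusted p = 5.53e-26 and 4.5e-28, and adjusted p = 0.00776 and 0.00545 with an estimated correlation. The median log2 difference of that list in the distal colon was -6.23, or -5.59 with the 5 members absent from one side held at their bound. Ptprc fell by 4.90 ± 0.60 in the distal colon (adjusted p = 2.18e-08) and Laptm5, a lysosomal protein of blood cells, fell by 7.86 ± 0.75 in the proximal colon (adjusted p = 2.61e-11; -7.16 without proximal colon GFP-negative replicate 3). The called genes were 5912 (2640 higher, 3272 lower) in the proximal and 5875 (2620 higher, 3255 lower) in the distal colon. With only the 2 groups compared in the fit, the proximal colon count was 2899.

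**Figure D2:**
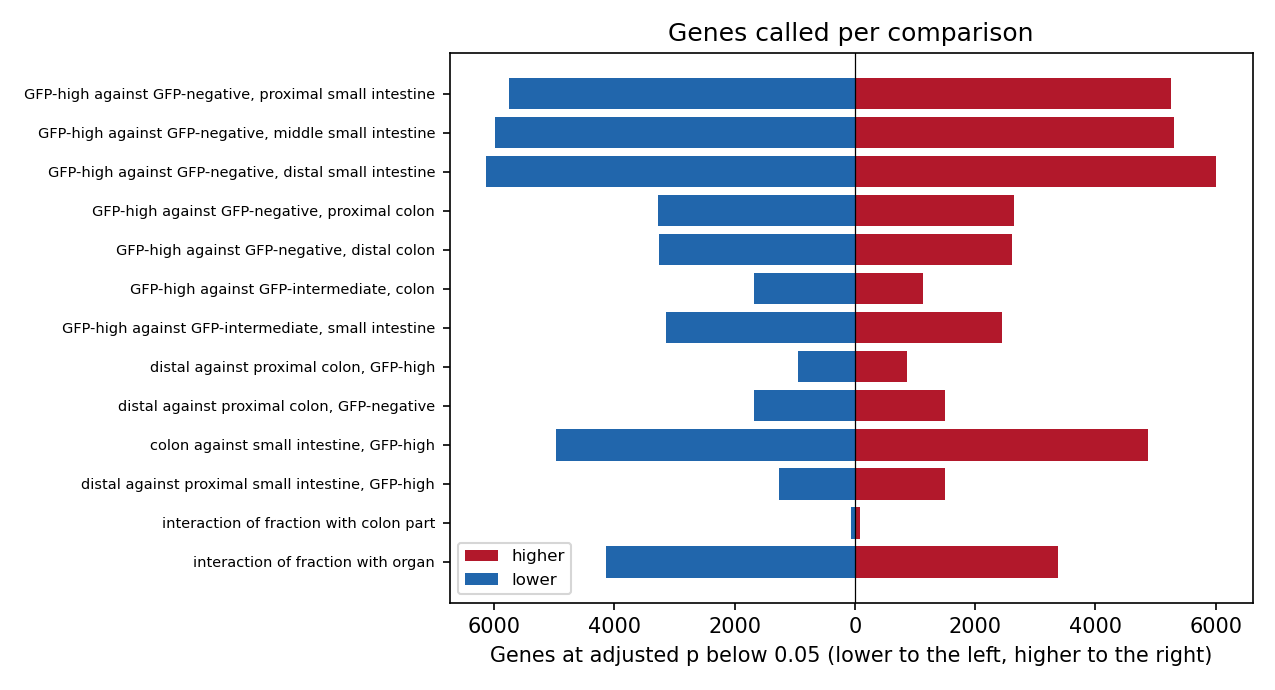
Number of genes called at an adjusted p below 0.05 in each of the 13 comparisons, lower to the left and higher to the right of 0. The middle and distal small intestine give 11290 and 12137 calls for GFP-high against GFP-negative, the proximal and distal colon 5912 and 5875.

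In all 5 parts alike, 1534 genes were higher and 1545 lower in GFP-high cells, against 3.9 and 7.54 if the parts were independent. With only the groups compared in each fit the counts were 864 and 857, and without the libraries numbered 1 the lower count was 848. Genes higher in all 3 small intestinal parts numbered 3820 (307 if independent), and in both colon parts 1799 (296 if independent).

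**Figure D3:**
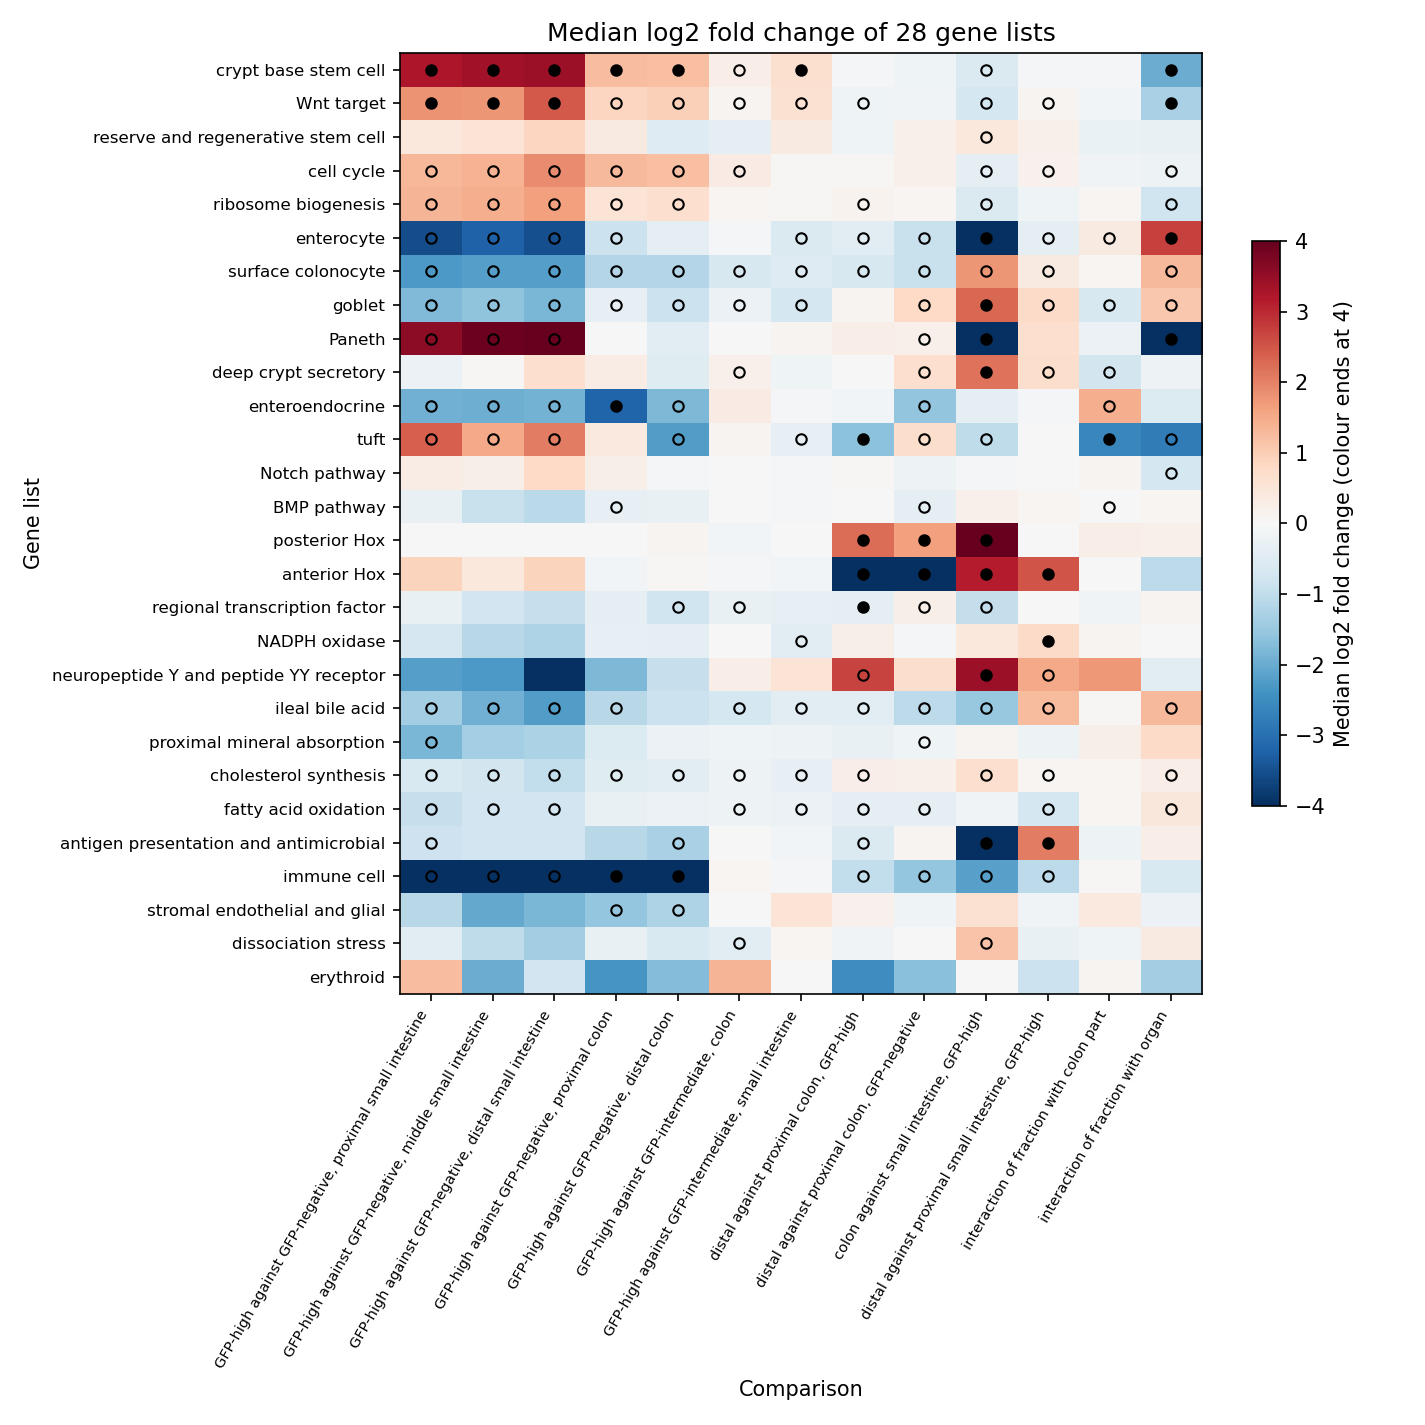
Median log2 difference of the members of the 28 gene lists in the 13 comparisons, with colours that end at 4; open dots mark list tests at an adjusted p below 0.05 and filled dots those that also pass with an estimated correlation. For GFP-high against GFP-negative, the crypt base stem cell list lies at 3.22, 3.36 and 3.41 in the small intestine and at 1.24 and 1.20 in the colon, and the tuft list at 2.40 in the proximal small intestine and -2.22 in the distal colon.

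GFP-high and GFP-intermediate cells differed by smaller steps. Over the colon, Lgr5 was higher by 1.28 ± 0.19, adjusted p = 5.28e-05, and Smoc2 (0.79 ± 0.10, adjusted p = 8.92e-07), Picalm, a clathrin adaptor (0.54 ± 0.10, adjusted p = 0.000365), and Cep70, a centrosomal protein (0.72 ± 0.13, adjusted p = 0.000506), followed. Klf4, a transcription factor of differentiated epithelium, fell by 1.14 ± 0.18 (adjusted p = 0.000121) and Smad7, an inhibitor of TGF-beta signalling, fell by 1.04 ± 0.17 (adjusted p = 0.000222). Nox1 (0.46 ± 0.36, adjusted p = 0.455) and Npy1r (0.77 ± 0.35, adjusted p = 0.148) were not called, but were with only the groups compared in the fit (adjusted p = 0.0136 and 0.0193). Of the crypt base stem cell list, 8 rose, 0 fell and 24 were not called (10 and 0 adjusted over the list alone). For the crypt base stem cell set, adjusted p = 8.4e-06, and adjusted p = 0.191 with an estimated correlation. Of the cell cycle genes, 11 rose, 0 fell and 27 were not called (17 and 0 adjusted over the list alone). For the cell cycle set, adjusted p = 5.58e-08, and adjusted p = 0.448 with an estimated correlation. Of the surface colonocyte genes, 0 rose, 10 fell and 15 were not called (0 and 12 adjusted over the list alone). For the surface colonocyte set, adjusted p = 8.34e-07, and adjusted p = 0.144 with an estimated correlation. The count of 2811 called genes (1128 higher, 1683 lower) rested on few libraries. It was 1053 without proximal colon GFP-high replicate 1, and 1569 and 1789 without distal colon GFP-high replicates 3 and 1 in turn. Without all libraries numbered 1 it was 71, and with only the groups compared 4820.

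Over the small intestine, Lgr5 was higher in GFP-high than in GFP-intermediate cells by 2.00 ± 0.16, adjusted p = 2.76e-13, with Tnfrsf19 (1.70 ± 0.15, adjusted p = 4.35e-12) and Sorbs2, a cytoskeletal adaptor (1.35 ± 0.12, adjusted p = 2.53e-11). Lmna, which encodes lamin A, fell by 1.11 ± 0.11 (adjusted p = 3.26e-10) and Ihh, the hedgehog ligand of differentiated epithelium, fell by 1.21 ± 0.18 (adjusted p = 1.47e-06). Nox1 was not called (0.20 ± 0.30, adjusted p = 0.731), and its sign turned without proximal small intestine GFP-high replicate 4 (-0.01). Of the crypt base stem cell list, 26 rose, 0 fell and 6 were not called (29 and 0 adjusted over the list alone). The crypt base stem cell list tested at adjusted p = 6.17e-24, and at adjusted p = 0.00182 with an estimated correlation. Of the goblet genes, 0 rose, 16 fell and 7 were not called (0 and 18 adjusted over the list alone). For the goblet set, adjusted p = 6.88e-14, and adjusted p = 0.0615 with an estimated correlation. Of the Paneth genes, 0 rose, 0 fell and 20 were not called (0 and 0 adjusted over the list alone). Paneth genes as a set gave adjusted p = 0.6, and adjusted p = 0.895 with an estimated correlation. Of the tuft genes, 0 rose, 9 fell and 16 were not called (0 and 10 adjusted over the list alone). Tuft genes as a set gave adjusted p = 0.000463, and adjusted p = 0.469 with an estimated correlation. In all, 5575 genes were called (2441 higher, 3134 lower), and 3392 without the libraries numbered 1.

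The comparison of the colon parts asked which genes tell distal from proximal GFP-high cells, and Hox and other patterning genes were among them. Hoxd13 was higher in the distal colon by 9.07 ± 0.79, adjusted p = 3.59e-08, and Hoxb13 by 5.26 ± 0.55, adjusted p = 1.27e-08. Osr2 (-8.37 ± 0.66, adjusted p = 4.81e-14) and Tbx3 (-6.15 ± 0.60, adjusted p = 3.39e-11), transcription factors of embryonic patterning, and Hoxb4 (-7.47 ± 0.82, adjusted p = 1.12e-09) were lower. Single libraries moved these values: without proximal colon GFP-high replicate 3 Hoxd13 was 12.17, and without replicate 4 Hoxb13 was 6.33. Without distal colon GFP-high replicate 3, Tbx3 and Hoxb4 were -7.28 and -8.8, and Osr2 had no distal count. Of the posterior Hox list, 8 rose, 0 fell and 3 were not called (8 and 1 adjusted over the list alone). The posterior Hox list tested at adjusted p = 2.06e-27, and at adjusted p = 2.06e-08 with an estimated correlation. Of the anterior Hox list, 0 rose, 9 fell and 10 were not called (1 and 11 adjusted over the list alone). The anterior Hox list tested at adjusted p = 3.94e-15, and at adjusted p = 0.00053 with an estimated correlation. Its median was -5.77, or -3.86 with the member absent from one side at its bound. Of the regional transcription factor list, 1 rose, 7 fell and 15 were not called (2 and 9 adjusted over the list alone). The regional transcription factor list tested at adjusted p = 2e-06, and at adjusted p = 0.0335 with an estimated correlation. Slc10a2, which takes bile acid up from the lumen, was lower in the distal colon (-6.19 ± 0.74, adjusted p = 9.03e-09; -7.18 without distal colon GFP-high replicate 2). Of the tuft list, 0 rose, 18 fell and 7 were not called (0 and 21 adjusted over the list alone). For the tuft set, adjusted p = 1.56e-23, and adjusted p = 0.0218 with an estimated correlation. These included Trpm5 (-2.15 ± 0.28, adjusted p = 5.3e-08), the cyclooxygenase gene Ptgs1 (-2.85 ± 0.34, adjusted p = 9.03e-09) and Il17rb, the receptor for interleukin 25 (-2.52 ± 0.31, adjusted p = 2.07e-08). The cell cycle genes gave no call: 0 rose, 0 fell and 38 were not called (0 and 0 adjusted over the list alone). The cell cycle list tested at adjusted p = 0.948, and at adjusted p = 0.99 with an estimated correlation. Lgr5 (-0.38 ± 0.26, adjusted p = 0.503) and Nox1 (1.15 ± 0.51, adjusted p = 0.195) were not called, but Nox1 was with only the groups compared in the fit (1.13, adjusted p = 0.00219). The comparison called 1821 genes, 874 higher and 947 lower in the distal colon.

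GFP-negative cells of the colon were divided along the same axis. Osr2 (-8.21 ± 0.65, adjusted p = 3.43e-14) and Slc10a2 (-7.12 ± 0.75, adjusted p = 2.95e-10) were lower and Hoxb13 (5.47 ± 0.56, adjusted p = 5.13e-09) higher in the distal part. Osr2 was -9.85 without distal colon GFP-negative replicate 3 and Slc10a2 -8.06 without distal colon GFP-negative replicate 4. Hoxd13, with no count in the proximal libraries, was at least 1654-fold higher in the distal ones. Sct, for the hormone secretin (-5.00 ± 0.51, adjusted p = 9.44e-11), and Tph1 (-3.70 ± 0.44, adjusted p = 7.66e-09) were lower; of the enteroendocrine list, 1 rose, 18 fell and 8 were not called (2 and 19 adjusted over the list alone). For the enteroendocrine set, adjusted p = 6.72e-11, and adjusted p = 0.0997 with an estimated correlation. Of the goblet genes, 16 rose, 0 fell and 7 were not called (17 and 0 adjusted over the list alone). The goblet list tested at adjusted p = 1.66e-09, and at adjusted p = 0.13 with an estimated correlation. Of the posterior Hox list, 8 rose, 1 fell and 2 were not called (8 and 1 adjusted over the list alone). Posterior Hox genes as a set gave adjusted p = 7.57e-21, and adjusted p = 3.28e-07 with an estimated correlation. Of the anterior Hox list, 0 rose, 11 fell and 8 were not called (0 and 11 adjusted over the list alone). Anterior Hox genes as a set gave adjusted p = 1.27e-11, and adjusted p = 0.00229 with an estimated correlation. Its median was -5.67, or -4.91 with the members absent from one side at their bound. Leukocyte genes moved with these: of the immune cell list, 1 rose, 10 fell and 14 were not called (3 and 14 adjusted over the list alone). For the immune cell set, adjusted p = 0.0125, and adjusted p = 0.564 with an estimated correlation. Lgr5 fell by 0.92 ± 0.27 (adjusted p = 0.0158), a call that ended without proximal colon GFP-negative replicate 1 (adjusted p = 0.102), without distal colon GFP-negative replicate 3 (adjusted p = 0.0855), without the libraries numbered 1 (adjusted p = 0.159) and with only the groups compared (adjusted p = 0.0653). In all, 3168 genes were called (1493 higher, 1675 lower; 1709 with only the groups compared). Of the genes called in GFP-high cells, 605 were also higher and 622 also lower in the distal GFP-negative cells (55.9 and 67.9 if independent), and 14 were called in opposite directions.

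Genes that were both higher in the GFP-high cells of one colon part than in its GFP-negative cells and higher than in the GFP-high cells of the other part address the regional stem cell populations named in the study's title. The distal ones numbered 127 and included Npy1r (3.97 ± 0.56, adjusted p = 5.45e-07 over the proximal GFP-high cells), Trf, which encodes transferrin (6.54 ± 0.55, adjusted p = 3.26e-13), and the glycosyltransferase genes B4galnt3 (3.67 ± 0.20, adjusted p = 1.37e-19) and Fut9 (3.42 ± 0.36, adjusted p = 6.24e-08). The proximal ones numbered 130 and included Kif26b (-4.18 ± 0.57, adjusted p = 2.38e-07), Pipox, which oxidises pipecolic acid (-2.72 ± 0.23, adjusted p = 2.08e-13), and the nuclear receptor Nr2e3 (-2.52 ± 0.33, adjusted p = 6.28e-08). Nox1 met the first criterion in both parts and the second in neither. Of the distal genes 72, and of the proximal genes 67, showed the same difference between the parts in GFP-negative cells, and 11 and 10 passed the test of the interaction. Both criteria share GFP-high libraries, so the 98 and 107 that independence would give are no fair baseline. In a single split with separate GFP-high libraries for each, of 25654 genes, 61 were distal (29 if independent) and 34 proximal (37). All 5 simulations without effects gave 0 and cannot test an excess. The distal count was 75 and 84 without distal colon GFP-high replicates 3 and 1 in turn. The distal and proximal counts were 220 and 244 under the newer quasi-likelihood method and 43 and 74 with a fold of at least 2 in addition.

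**Figure D4:**
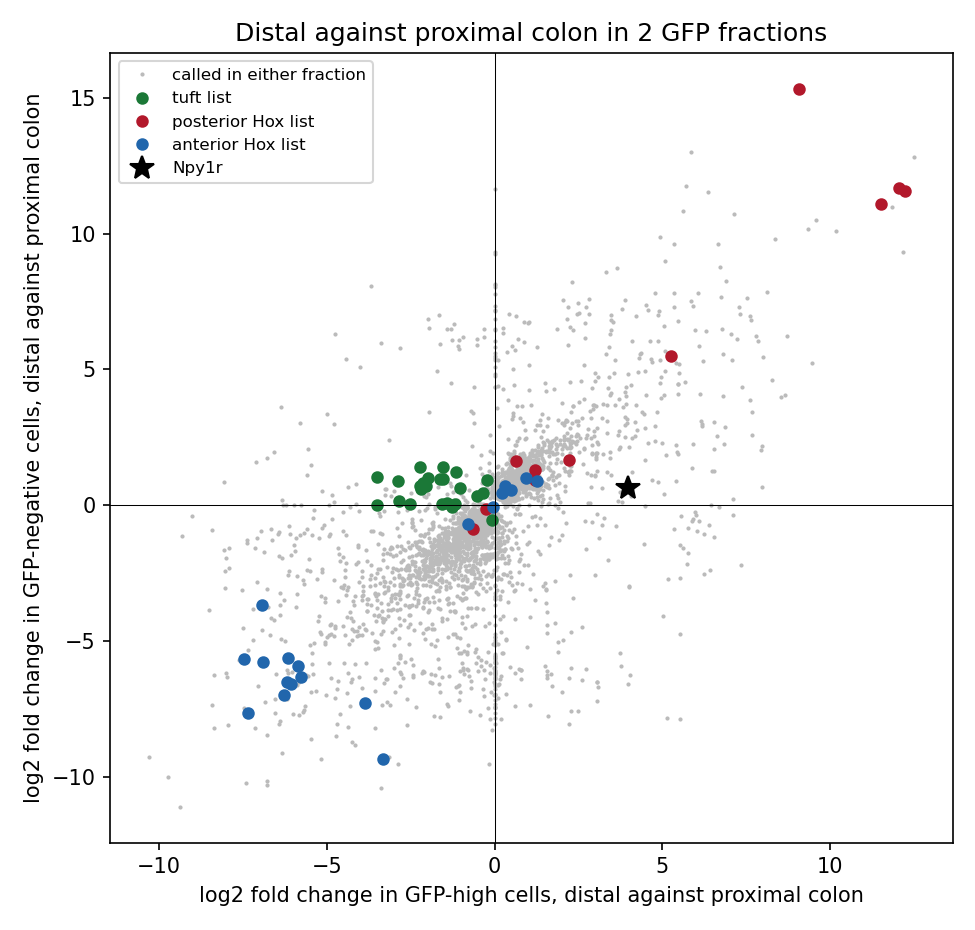
Log2 difference of distal over proximal colon in GFP-high cells against the same in GFP-negative cells for genes called in either fraction, with the tuft and the 2 Hox lists in colour and Npy1r as a star. Npy1r lies at 3.97 and 0.64.

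The interaction tested whether the GFP-high to GFP-negative difference itself differed between the colon parts, and 15 of its 144 called genes, all with negative values, were on the tuft list. Dclk1 stood at 87.95 ± 14.99 CPM in GFP-high and 71.1 ± 27.1 CPM in GFP-negative cells of the proximal colon, and at 21.2 ± 3.84 and 116 ± 24.7 CPM in the distal colon, where it fell by 2.45 ± 0.30 (adjusted p = 2.53e-08) together with Trpm5 (-2.29 ± 0.28, adjusted p = 2.11e-08) and Avil, which encodes advillin (-2.21 ± 0.29, adjusted p = 1.31e-07). The distal minus proximal difference was -2.75 ± 0.41, adjusted p = 5.3e-05 for Dclk1, -2.88 ± 0.38, adjusted p = 9.33e-06 for Trpm5, -2.92 ± 0.41, adjusted p = 2.24e-05 for the G protein regulator Rgs13 and -2.91 ± 0.39, adjusted p = 9.96e-06 for Sh2d7. Of the tuft list, 4 and 22 of the 25 fell, 5 and 0 rose and 16 and 3 were not called (4 and 22 fell adjusted over the list alone) in the proximal and distal colon in turn. The tuft list tested at adjusted p = 0.0952 and 5.2e-17, and at adjusted p = 0.751 and 0.0615 with an estimated correlation. In the interaction, 0 rose, 15 fell and 10 were not called (0 and 22 adjusted over the list alone). Tuft genes as a set gave adjusted p = 1.23e-49, and adjusted p = 0.00053 with an estimated correlation. Rac2, a GTPase of blood cells (-3.82 ± 0.70, adjusted p = 0.0011), was more negative in the distal colon as well. More positive were Trf (3.49 ± 0.64, adjusted p = 0.00104), Ambp, the precursor of alpha-1-microglobulin (3.84 ± 0.74, adjusted p = 0.00231), and the tachykinin gene Tac1 (2.94 ± 0.46, adjusted p = 0.0001). Without proximal colon GFP-negative replicate 3, Rac2 was -4.46 and Trf 2.81. Of the enteroendocrine list, 3 rose, 0 fell and 24 were not called (12 and 0 adjusted over the list alone). The enteroendocrine list tested at adjusted p = 3.49e-14, and at adjusted p = 0.0615 with an estimated correlation. Of the goblet list, 0 rose, 0 fell and 23 were not called (0 and 1 adjusted over the list alone). Goblet genes as a set gave adjusted p = 2.27e-09, and adjusted p = 0.134 with an estimated correlation. Lgr5 (0.54 ± 0.38, adjusted p = 0.862) and Nox1 (0.07 ± 0.72, adjusted p = 1) were not called. The test called 144 genes (84 higher, 60 lower), 83 without proximal colon GFP-negative replicate 3, 91 without distal colon GFP-negative replicate 2, 71 without the libraries numbered 1, 52 with only the groups compared and 275 by DESeq2. Ptprc in the proximal colon GFP-negative libraries ran from 48.5 to 429 CPM.

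**Figure D5:**
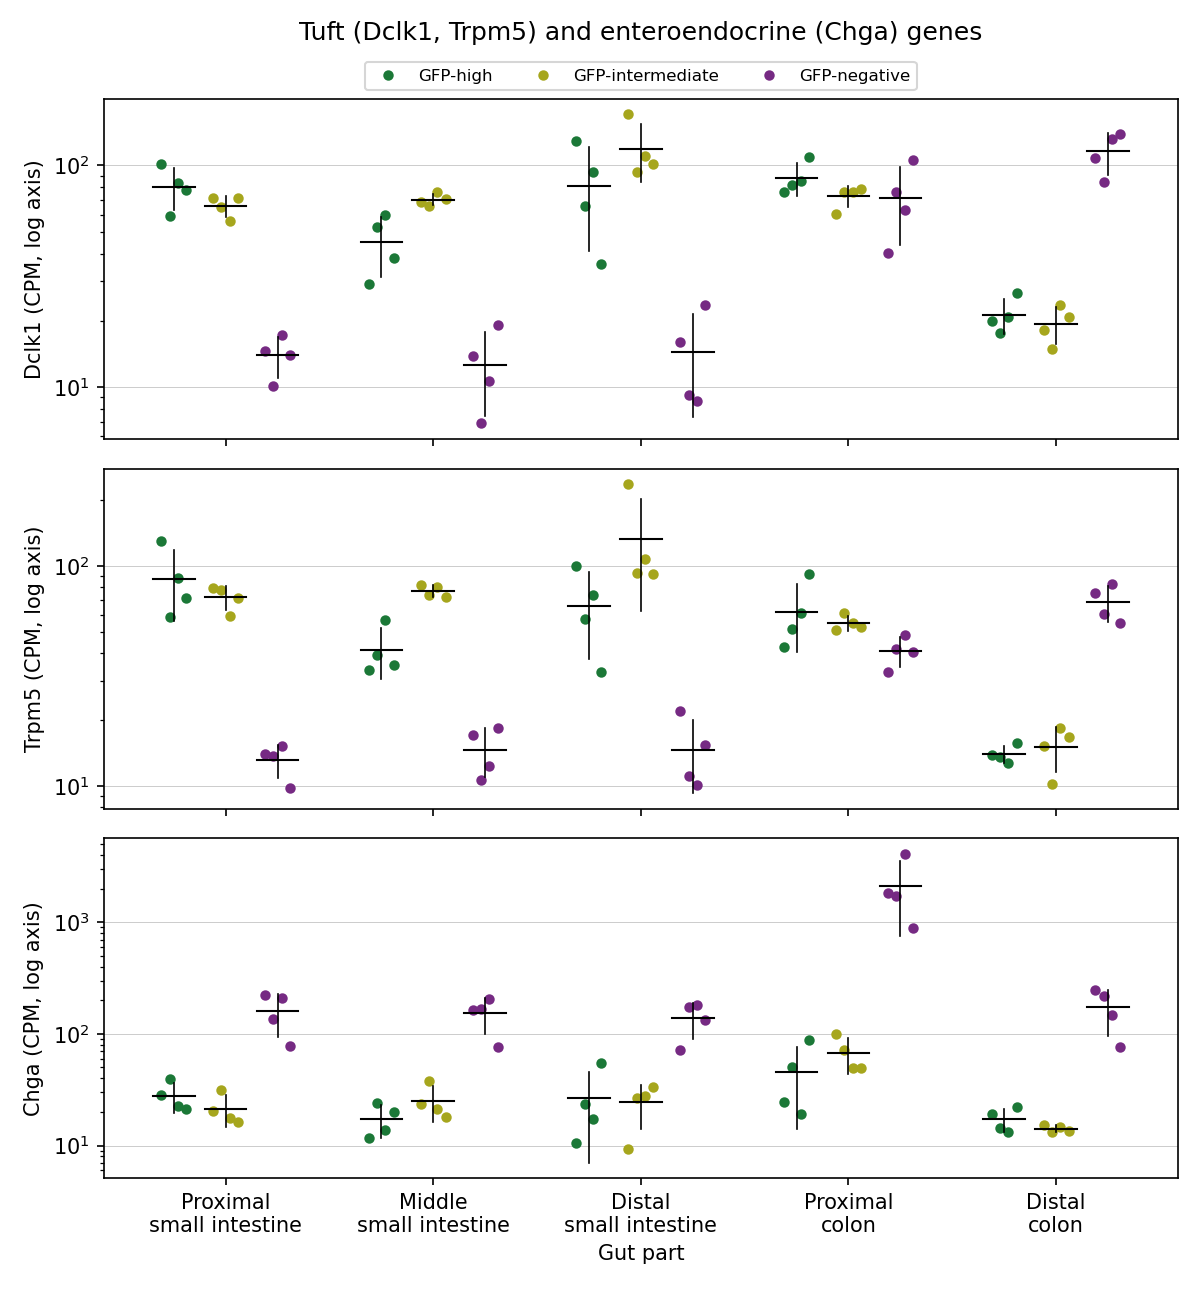
Normalised counts (CPM) of the tuft genes Dclk1 and Trpm5 and the enteroendocrine gene Chga by gut part and GFP fraction, on a log axis; points are libraries, horizontal bars the mean and vertical bars the SD of 4. In the proximal colon the GFP-high mean of Dclk1 is 87.95 CPM and the GFP-negative mean 71.1 CPM, in the distal colon 21.2 and 116 CPM.

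Colon and small intestinal GFP-high cells differed in genes known to pattern the gut and in lineage genes. The colon cells were higher in Foxd2 (8.44 ± 0.42, adjusted p = 1.47e-23), Nox1 (3.01 ± 0.33, adjusted p = 6.81e-11) and Npy1r (10.02 ± 0.51, adjusted p = 1.71e-22). Npy1r had few counts in the small intestine, and its difference was 10.86 without proximal small intestine GFP-high replicate 2 and 11.06 without middle small intestine GFP-high replicate 3. Hoxb13, Hoxa13 and the fucosyltransferase gene Fut9 had no count in the 12 small intestinal libraries, and the mean of the 8 colon libraries was at least 2974-fold higher, at least 868-fold higher and at least 2559-fold higher; the distal colon weighs most in the colon mean for Hoxb13, and for Fut9 and Npy1r, which stood 3.42 and 3.97 above the proximal colon. The transcription factors Gata4 (-8.74 ± 0.42, adjusted p = 3.98e-24) and Gata5 (-7.58 ± 0.29, adjusted p = 2.92e-28) were lower, with Sis, the sucrase-isomaltase (-7.81 ± 0.36, adjusted p = 8.64e-25), and Mttp (-5.36 ± 0.20, adjusted p = 1.35e-28). Lyz1 (-13.09 ± 0.47, adjusted p = 4.02e-29) was lower, and Defa20, an alpha-defensin with no count in the colon libraries, was at least 9794-fold lower. Lgr5 was lower (-0.86 ± 0.17, adjusted p = 5.35e-05).

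Of the enterocyte list, 0 rose, 27 fell and 1 was not called (1 and 27 adjusted over the list alone). Enterocyte genes as a set gave adjusted p = 1.53e-28, and adjusted p = 0.00635 with an estimated correlation. Of the Paneth list, 3 rose, 17 fell and 0 were not called (3 and 17 adjusted over the list alone). For the Paneth set, adjusted p = 4.77e-22, and adjusted p = 0.00278 with an estimated correlation. Of the goblet list, 20 rose, 1 fell and 2 were not called (21 and 1 adjusted over the list alone). For the goblet set, adjusted p = 1.51e-18, and adjusted p = 0.023 with an estimated correlation. These included Klk1, a kallikrein (4.66 ± 0.18, adjusted p = 3.85e-28); of the deep crypt secretory list, 9 rose, 1 fell and 0 were not called (9 and 1 adjusted over the list alone). The deep crypt secretory list tested at adjusted p = 8.34e-07, and at adjusted p = 0.00868 with an estimated correlation. The list includes the receptor tyrosine kinase Kit (2.09 ± 0.13, adjusted p = 2.97e-19). Of the posterior Hox list, 8 rose, 0 fell and 3 were not called (8 and 0 adjusted over the list alone). For the posterior Hox set, adjusted p = 2.49e-25, and adjusted p = 3.27e-08 with an estimated correlation. Its median was 10.48, or 10.12 with the members absent from one side at their bound. Of the crypt base stem cell list, 4 rose, 20 fell and 8 were not called (4 and 20 adjusted over the list alone). Crypt base stem cell genes as a set gave adjusted p = 6.24e-08, and adjusted p = 0.105 with an estimated correlation. Of the antigen presentation and antimicrobial list, 1 rose, 12 fell and 3 were not called (1 and 12 adjusted over the list alone). The antigen presentation and antimicrobial list tested at adjusted p = 4.87e-10, and at adjusted p = 0.0282 with an estimated correlation. Members included the MHC class II gene H2-Ab1 (-5.92 ± 0.43, adjusted p = 4.77e-17) and the lectin gene Reg3a (-8.81 ± 0.53, adjusted p = 5.69e-19). Dissociation stress genes moved with the organ: 15 rose, 0 fell and 2 were not called (15 and 0 adjusted over the list alone). The dissociation stress list tested at adjusted p = 2e-05, and at adjusted p = 0.275 with an estimated correlation. These included the heat shock genes Hspa1a (6.04 ± 0.56, adjusted p = 1.69e-13) and Hspa1b (4.81 ± 0.33, adjusted p = 6.06e-18). The comparison called 9847 genes (4878 higher, 4969 lower in the colon). Without the libraries numbered 1, which stand apart in Xist, it called 8357, of which 8068 were among the 9847.

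The interaction with the organ tested whether the GFP-high to GFP-negative difference differed between colon and small intestine. It was more negative in the colon for Lgr5 (-2.47 ± 0.25, adjusted p = 1.29e-11), for Slc14a1, a urea transporter on the stem list (-9.66 ± 0.61, adjusted p = 5.07e-18), and for Lyz1 (-6.28 ± 0.43, adjusted p = 6.38e-17), Dclk1 (-3.35 ± 0.27, adjusted p = 1.2e-14) and Trpm5 (-2.99 ± 0.25, adjusted p = 3.96e-14). It was more positive for Npy1r (4.58 ± 0.69, adjusted p = 4.54e-07), Mme, which encodes neprilysin (5.87 ± 0.47, adjusted p = 1.13e-14), Slc2a2, the glucose transporter GLUT2 (5.29 ± 0.82, adjusted p = 7.05e-07), and the cytokine gene Il33 (4.69 ± 0.53, adjusted p = 2.71e-10); Nox1 was not called (-0.91 ± 0.47, adjusted p = 0.145). Npy1r, with few GFP-high counts in the small intestine, was 5.4 without proximal small intestine GFP-high replicate 2 and 5.62 without middle small intestine GFP-high replicate 3. Slc14a1 was -11.94 without distal colon GFP-high replicate 3, and Il33 5.5 without proximal colon GFP-negative replicate 4. Of the crypt base stem cell list, 1 rose, 27 fell and 4 were not called (1 and 28 adjusted over the list alone). For the crypt base stem cell set, adjusted p = 1.78e-28, and adjusted p = 0.00053 with an estimated correlation. Of the Wnt target list, 2 rose, 18 fell and 4 were not called (2 and 18 adjusted over the list alone). For the Wnt target set, adjusted p = 8.53e-11, and adjusted p = 0.0078 with an estimated correlation. Of the enterocyte list, 24 rose, 0 fell and 4 were not called (25 and 0 adjusted over the list alone). For the enterocyte set, adjusted p = 4.77e-22, and adjusted p = 0.0174 with an estimated correlation. Of the Paneth list, 0 rose, 12 fell and 8 were not called (0 and 12 adjusted over the list alone). The Paneth list tested at adjusted p = 5.47e-18, and at adjusted p = 0.00776 with an estimated correlation. Of the tuft list, 0 rose, 21 fell and 4 were not called (0 and 21 adjusted over the list alone). For the tuft set, adjusted p = 1.31e-16, and adjusted p = 0.0622 with an estimated correlation. In all, 7515 genes were called (3381 higher, 4134 lower).

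Within the small intestine, distal GFP-high cells differed from proximal ones in Hox, bile acid and host defence genes. Hoxb8 was higher by 9.81 ± 1.05, adjusted p = 1.09e-09, with proximal counts only in GFP-high replicate 4. Hoxb9, with no count in the proximal libraries, was at least 673-fold higher. Pdx1, the transcription factor of duodenum and pancreas (-8.79 ± 0.74, adjusted p = 6.9e-13), and Onecut2 (-6.43 ± 0.61, adjusted p = 1.52e-11) were lower. The pancreatic enzyme genes Pnlip and Ctrb1 were called lower as well; whether pancreas was carried along in the dissection was not tested, so these are not read as expression by GFP-high cells. Pnlip had no count in the distal libraries and 0.131 to 28.9 CPM in the proximal ones (adjusted p = 0.0285), a call that ended without GFP-high replicate 2 of the proximal part (adjusted p = 0.0634), without GFP-high replicate 1 (adjusted p = 0.0828), 2 (adjusted p = 0.0706), 3 (adjusted p = 0.0676) or 4 (adjusted p = 0.0553) of the distal part, without the libraries numbered 1 (adjusted p = 0.0985) and under the newer quasi-likelihood method (adjusted p = 0.0855). Ctrb1 (adjusted p = 0.00221) averaged 14.61 CPM in the proximal part and had too few counts in the distal part for a ratio. Fabp6, the ileal bile acid-binding protein (7.40 ± 0.90, adjusted p = 1.74e-08), and Slc10a2 (5.88 ± 0.73, adjusted p = 2.34e-08) were higher, while the fatty acid-binding protein gene Fabp1 (-4.46 ± 0.59, adjusted p = 1.49e-07) was lower. Of the anterior Hox list, 9 rose, 2 fell and 8 were not called (11 and 2 adjusted over the list alone). For the anterior Hox set, adjusted p = 2.79e-06, and adjusted p = 0.0389 with an estimated correlation. Of the ileal bile acid list, 6 rose, 2 fell and 2 were not called (6 and 3 adjusted over the list alone). The ileal bile acid list tested at adjusted p = 0.000706, and at adjusted p = 0.19 with an estimated correlation. Nox1 (4.06 ± 0.58, adjusted p = 7.14e-07), the dual oxidase gene Duox2 (3.75 ± 0.34, adjusted p = 5.7e-12) and its maturation factor Duoxa2 (4.40 ± 0.49, adjusted p = 1.9e-09) were higher, Nox1 by 4.69 without proximal small intestine GFP-high replicate 4; of the NADPH oxidase list, 7 rose, 0 fell and 7 were not called (10 and 0 adjusted over the list alone). The NADPH oxidase list tested at adjusted p = 3.07e-08, and at adjusted p = 0.000649 with an estimated correlation. Of the antigen presentation and antimicrobial list, 12 rose, 0 fell and 4 were not called (12 and 0 adjusted over the list alone). Antigen presentation and antimicrobial genes as a set gave adjusted p = 3.76e-11, and adjusted p = 0.0184 with an estimated correlation. The list includes the lectin gene Reg3g (3.88 ± 0.69, adjusted p = 4.57e-05). Of the goblet list, 12 rose, 0 fell and 11 were not called (13 and 1 adjusted over the list alone). The goblet list tested at adjusted p = 4.71e-09, and at adjusted p = 0.141 with an estimated correlation. Members included the mucin gene Muc2 (1.75 ± 0.30, adjusted p = 3.13e-05). Of the fatty acid oxidation list, 0 rose, 9 fell and 13 were not called (0 and 19 adjusted over the list alone). The fatty acid oxidation list tested at adjusted p = 1.35e-10, and at adjusted p = 0.129 with an estimated correlation. Npy1r, with few counts, was not called (adjusted p = 0.345). Lgr5 was higher by 0.80 ± 0.27, adjusted p = 0.0381, a call that ended without GFP-high replicate 2 (adjusted p = 0.0971), 3 (adjusted p = 0.105) or 4 (adjusted p = 0.0983) of the proximal part, without GFP-high replicate 1 (adjusted p = 0.0709), 2 (adjusted p = 0.0805) or 3 (adjusted p = 0.0862) of the distal part, and without the libraries numbered 1 (adjusted p = 0.055). The comparison called 2759 genes (1493 higher, 1266 lower), 1566 without distal small intestine GFP-high replicate 1, 1186 without the libraries numbered 1 and 4996 with only the groups compared.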

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

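The tests of the explanations in this part were chosen only after the results they test were seen; for fewer libraries, the prediction was set down before the counts without numbers 2, 3 and 4 were run.

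Tuft genes set the 2 colon parts apart: their GFP-high to GFP-negative difference differed between proximal and distal colon, by -2.75 for Dclk1 and -2.88 for Trpm5. A single library as the source is argued against, since 11 or more tuft genes had a called negative interaction in each of 16 fits without 1 library, against 15 in the full fit. Tuft cells collected in the proximal GFP-high gate, which would keep out cells without Lgr5-driven eGFP, stay open: 75% of the 24 tuft list members at 1 CPM or more there were lower in the distal GFP-high cells, which is below the 80% set for this explanation and restates the pattern, so it decides nothing. The levels were Dclk1 at 87.95 and Trpm5 at 61.7 CPM in the proximal ones. Expression of these genes by the cells with the most Lgr5 predicts a step from GFP-intermediate to GFP-high; the tuft list's median step was 0.17 with 0 of 24 called, but the stem list's own was 0.14 with 1 of 32 called, while Lgr5 rose by 1.10 ± 0.27. These cannot be told apart from sorted bulk RNA, because no value here separates a few tuft cells from low expression in many cells.

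Paneth genes were higher in the GFP-high cells of all 3 small intestinal parts (lowest list median 3.58). Evenly spread free RNA predicts no difference, so this restates the pattern. Reads shared between alpha-defensin copies are excluded as the whole source, since the 12 list members outside that family still had a lowest median of 2.71. Paneth cells collected with the GFP-high cells stay open: 94.4% of the 18 list members at 10 CPM or more were higher in all 3 parts, but this restates the pattern and decides nothing. Lyz1 stood at 5114 to 9147 CPM. The eGFP gate would keep out Paneth cells without eGFP or stem cell neighbours, and doublets were not tested. No biological explanation, such as Paneth gene expression by stem cells, was tested.

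The libraries numbered 1 stood apart in Xist, which inactive X chromosomes express, in 15 of 15 groups. A library stood apart in Y-linked Ddx3y in 5 of 15 groups by the measure used, the gap to the next library as a share of the group's range, which the spread of the other 3 libraries can hide. Both genes were chosen after their values were seen. Xist stood at 404 to 2110 CPM in the 9 small intestinal and at 156 to 487 CPM in the 6 colon libraries numbered 1, and at no more than 1.94 CPM in the others. Ddx3y was 0 in the small intestinal libraries numbered 1 (41.3 to 69 CPM in numbers 2 to 4). It was at least 40.1 CPM in the colon ones (48.7 to 68.9 CPM in numbers 2 to 4). Colon number 1 held both genes, which argues against a single sex behind it and the same animals in both organs. The sex difference as the source of the colon against small intestine calls is argued against: 81.9% of them stayed called in the same direction without these libraries. For GFP-high against GFP-intermediate in the colon, 70 of 2811 stayed called. Log2 differences of the 2811 correlated at 0.99 and 100% kept their sign, but the fits share libraries, so this decides nothing. Fewer libraries alone do not set the count, which without numbers 2, 3 or 4, also at 45 libraries, was 754, 8 and 4443. Their part in the lost calls stays open, and number 1 is not the only one on which calls rest.

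Of 150 tests of a library against its group, 12 stood out, where chance gives about 1 in 20, or 7.5. The total count of proximal small intestine GFP-intermediate replicate 4 was 95809663, the others of its group 55411864 to 61434598. Lgr5 in proximal small intestine GFP-high replicate 1 was 405 CPM, the others 280.2 to 283.1. Npy1r was 19.96 CPM in proximal colon GFP-negative replicate 3 (others 7.58 to 9.17), 0.933 CPM in distal small intestine GFP-negative replicate 4 (others 0.285 to 0.370), 0.0448 CPM in middle small intestine GFP-high replicate 3 and 0.0286 CPM in proximal small intestine GFP-high replicate 2 (others 0). Ptprc was 4.94 CPM in proximal colon GFP-intermediate replicate 4 (others 5.63 to 5.73), 32.7 CPM in distal small intestine GFP-intermediate replicate 1 (others 10.2 to 12.5) and 8.74 CPM in proximal small intestine GFP-intermediate replicate 1 (others 5.39 to 5.52). Lyz1 was 0.114 CPM in proximal colon GFP-intermediate replicate 2 (others 0). Dclk1 was 60.7 CPM in proximal colon GFP-intermediate replicate 1 (others 75.7 to 78.1), and Trpm5 236 CPM in distal small intestine GFP-intermediate replicate 1 (others 91.8 to 108). The pancreatic genes Pnlip and Ctrb1, singled out after their values were seen, had 1 library apart in 4 of 15 groups each.

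The GFP-high to GFP-negative difference differed between the colon parts for 144 genes, with interaction values of 3.33 for Npy1r, 3.49 for Trf, -2.88 for Trpm5, -2.92 for Rgs13, -2.75 for Dclk1, 2.94 for Tac1, -2.91 for Sh2d7, 3.84 for Ambp and -3.82 for Rac2. For Npy1r the call ended without proximal colon GFP-negative replicate 3 (2.89, adjusted p = 0.0514), and without it Trf was 2.81 and Rac2 -4.46. It differed between colon and small intestine for 7515 genes, with values of -2.47 for Lgr5, 4.58 for Npy1r, -9.66 for Slc14a1, -6.28 for Lyz1, 5.87 for Mme, 6.28 for Cmah, 6.29 for Lrrk2, -3.35 for Dclk1, -2.99 for Trpm5, 5.29 for Slc2a2 and 4.69 for Il33. Npy1r was 5.4 without proximal small intestine GFP-high replicate 2 and 5.62 without middle small intestine GFP-high replicate 3, Slc14a1 -11.94 without distal colon GFP-high replicate 3 and Il33 5.5 without proximal colon GFP-negative replicate 4.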

How the results depend on the processing

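The newer quasi-likelihood form (legacy = FALSE) and the fits without all libraries of one number were chosen after the data were seen; the other alternatives were fixed beforehand. No called gene printed here turned its direction under any of them. DESeq2 size factors in place of TMM shifted the median of all genes in GFP-high against GFP-negative by -0.102, -0.078 and -0.127 in the proximal, middle and distal small intestine and by -0.058 and -0.044 in the proximal and distal colon, by construction, and left all counts within 1.5 times; so did no filter on low counts and the replicate block.
A fold of at least 2 in addition, which by its construction removes genes, left 6805, 7056 and 7827 genes for GFP-high against GFP-negative down the small intestine, 3057 and 2741 down the colon, 364 and 653 for GFP-high against GFP-intermediate in colon and small intestine, 1181 and 1895 for the colon parts in GFP-high and GFP-negative cells, 4564 for colon against small intestine, 1372 for the parts of the small intestine, 3376 for the interaction with organ, 372 shared higher, 880 shared lower, 43 regional distal and 74 regional proximal genes.
With only the groups compared, which re-estimates the spread from fewer libraries, the counts were 2899 for proximal colon GFP-high against GFP-negative, 4820 for GFP-high against GFP-intermediate in the colon, 1709 for the colon parts in GFP-negative cells, 4996 for the parts of the small intestine, 52 for the interaction with colon part, and 864 and 857 shared. Without the libraries numbered 1, GFP-high against GFP-intermediate gave 71 in the colon and 3392 in the small intestine. The small intestine parts gave 1186, the interaction with colon part 71, and 848 genes were shared lower. Fewer libraries alone do not set the first count, and no other cause was tested. The DESeq2 Wald test gave 275 for that interaction, and legacy = FALSE gave 220 distal and 244 proximal regional genes; the cause was not tested.
Leaving out each library in turn gave 1053 to 3837 for GFP-high against GFP-intermediate in the colon, 1566 to 2866 for the parts of the small intestine, 83 to 171 for the interaction with colon part and 75 to 152 regional distal genes; the other counts stayed within 1.5 times. Nox1, not called in either, ran from -0.01 to 0.45 for GFP-high against GFP-intermediate in the small intestine. In the interaction with colon part it ran from -0.09, without proximal colon GFP-negative replicate 2, to 0.24. It was -0.05 without proximal colon GFP-high replicate 1, and -0.03 and -0.01 without distal colon GFP-high and GFP-negative replicate 3.
Of the list tests, 34 were called with an estimated correlation and 180 with the replicate block, against 173. The 7 gained with the block were antigen presentation in the middle small intestine (adjusted p = 0.0741, block 0.0485), the proximal colon (0.0942, block 0.0425) and the interaction with colon part (0.102, block 0.0198), dissociation stress in the distal small intestine (0.0633, block 0.0417), fatty acid oxidation in the proximal colon (0.0597, block 0.0398), and mineral absorption for GFP-high against GFP-intermediate in the colon (0.0724, block 0.0236) and the interaction with organ (0.0627, block 0.0337). Beyond these and Npy1r in the proximal colon (adjusted p = 0.0576, block 0.0268) the block changed no call of a gene named here; the numbers of list members called were not counted again with it. Changes of 1.5-fold were mostly missed on simulated data.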

Other observations

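The tests of chance splits in this part were chosen after the counts they test were seen, except those for the genes shared by the 5 parts.

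Lists of regulators and metabolism added to the picture of the GFP-high cells. Cholesterol synthesis genes were lower in GFP-high than in GFP-negative cells: in the proximal, middle and distal small intestine and the proximal and distal colon in turn, of the list 15, 17, 21, 15 and 9 of the 22 fell, 0 rose and 7, 5, 1, 7 and 13 were not called (16, 19, 21, 17 and 15 fell adjusted over the list alone). The cholesterol synthesis list tested at adjusted p = 0.000288, 0.000379, 1.05e-06, 1.97e-05 and 0.000343, and at adjusted p = 0.391, 0.402, 0.211, 0.298 and 0.396 with an estimated correlation. Of the fatty acid oxidation list, 15, 13 and 14 of the 22 fell, 1, 2 and 2 rose and 6, 7 and 6 were not called (15, 13 and 14 fell adjusted over the list alone) down the small intestine. Fatty acid oxidation genes as a set gave adjusted p = 4.03e-05, 0.000365 and 0.00108, and adjusted p = 0.378, 0.444 and 0.469 with an estimated correlation. Of the ileal bile acid list, 6, 9 and 9 of the 10 fell, 0 rose and 4, 1 and 1 were not called (6, 9 and 9 fell adjusted over the list alone). Ileal bile acid genes as a set gave adjusted p = 0.00135, 0.00034 and 0.000131, and adjusted p = 0.211, 0.157 and 0.13 with an estimated correlation. In GFP-high cells of the colon against the small intestine, 17 rose, 0 fell and 5 were not called (19 and 0 adjusted over the list alone) of the cholesterol synthesis list. Cholesterol synthesis genes as a set gave adjusted p = 1.05e-06, and adjusted p = 0.211 with an estimated correlation. Pyy, the hormone that binds Npy1r and its relatives, was higher in the colon by 4.14 ± 0.38, adjusted p = 1.35e-13; of the neuropeptide Y and peptide YY receptor list, 3 rose, 0 fell and 1 was not called (3 and 0 adjusted over the list alone). The neuropeptide Y and peptide YY receptor list tested at adjusted p = 0.00537, and at adjusted p = 0.0384 with an estimated correlation.

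Other lists moved in part or not at all in GFP-high against GFP-negative cells of the proximal small intestine. Of the reserve and regenerative stem cell genes, 5 rose, 5 fell and 5 were not called (7 and 5 adjusted over the list alone). The reserve and regenerative stem cell list tested at adjusted p = 0.661, and at adjusted p = 0.751 with an estimated correlation. Of the Notch pathway, 7 rose, 2 fell and 7 were not called (7 and 2 adjusted over the list alone). The Notch pathway list tested at adjusted p = 0.149, and at adjusted p = 0.523 with an estimated correlation. Of the BMP pathway, 3 rose, 7 fell and 5 were not called (3 and 7 adjusted over the list alone). The BMP pathway list tested at adjusted p = 0.754, and at adjusted p = 0.88 with an estimated correlation. Its median was -0.30 and its mean 0.28. Of the proximal mineral absorption genes, 1 rose, 7 fell and 4 were not called (1 and 7 adjusted over the list alone). The proximal mineral absorption list tested at adjusted p = 0.00794, and at adjusted p = 0.275 with an estimated correlation. Of the stromal, endothelial and glial genes, 1 rose, 6 fell and 13 were not called (1 and 5 adjusted over the list alone) there. The stromal endothelial and glial list tested at adjusted p = 0.332, and at adjusted p = 0.701 with an estimated correlation. In the proximal colon 0 rose, 5 fell and 15 were not called (0 and 5 adjusted over the list alone). Stromal endothelial and glial genes as a set gave adjusted p = 0.0125, and adjusted p = 0.328 with an estimated correlation. Of the erythroid genes, 0 rose, 0 fell and 5 were not called (0 and 0 adjusted over the list alone). The erythroid list tested at adjusted p = 0.924, and at adjusted p = 0.966 with an estimated correlation. None of the dissociation stress genes told the colon parts apart in GFP-high cells: 0 rose, 0 fell and 17 were not called (0 and 0 adjusted over the list alone). Dissociation stress genes as a set gave adjusted p = 0.496, and adjusted p = 0.88 with an estimated correlation.

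Transcripts of the exocrine pancreas appeared in some libraries; Pnlip, for pancreatic lipase, and Ctrb1, for chymotrypsinogen, were singled out after their values were seen. Pnlip reached 178 CPM and Ctrb1 299 CPM in proximal small intestine GFP-intermediate replicate 2. In the GFP-intermediate libraries of the distal colon Pnlip ran from 5.33 to 71.1 CPM and Ctrb1 from 21.3 to 126 CPM. In the proximal colon GFP-negative libraries Pnlip was 0. Pancreas carried along in the dissection was not tested.

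The splits of the libraries were counted in fits of only the groups compared. For GFP-high against GFP-negative, 1 of 35 splits, the real one, gave as many genes in each part: 9319, 10375 and 9345 down the small intestine, with a highest other split of 0, and 2899 and 4594 down the colon, with highest others of 102 and 944, both from splits that part as many replicate pairs as the real one. For the colon parts the real counts were 1548 in GFP-high and 1709 in GFP-negative cells, and for the parts of the small intestine 4996, each against a highest other of 0 over 35 splits. Over 100 splits each, GFP-high against GFP-intermediate gave 4820 in the colon (highest other 1058) and 7817 in the small intestine (842), and colon against small intestine 9541 (583). The interaction with organ gave 6515 (highest other 1, over 40 splits), and the shared genes 864 higher and 857 lower (highest other 0, over 100 draws). These splits mixed the replicate numbers, so for each 39 more that part as many replicate pairs were counted. The highest were 4385 (near the real 4820), 4734, 3523 and 688 in turn, and draws gave 0 shared genes by construction. No other split reached the real counts, but for 2 groups only 7 others part as many pairs, too few to exclude chance. For the interaction with colon part, 4 of 100 splits, the real one included, gave as many as the real 52, with a highest other of 1231, and 2 of the 39 gave up to 1162. The split with 1231 exchanged the part labels of 100% of the GFP-negative and 25% of the GFP-high libraries, and that with 1162 of 0% and 75%. An exchange in mostly 1 fraction turns the interaction towards the difference between the parts itself, so these splits are no fair baseline, and chance is not taken as excluded for this count. Of 70 ways to deal the colon GFP-high libraries, the real one gave 91 distal and 75 proximal regional genes. Exchanged labels gave 417 and 451. The rest gave 0, as the colon parts' splits did, so this decides nothing.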
